A study of Danio rerio with 15 samples.

How the data were processed

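Gene expression was measured in livers of male zebrafish (Danio rerio) on 15 Agilent arrays with a single dye, Cy3. The labels place 6 arrays in a control group, 5 in a low and 4 in a high concentration group of chlorothalonil, a broad-spectrum fungicide. The concentrations themselves, the duration of exposure and the number of fish behind each array are not given in the sources used here, so p-values measure the spread between these samples, part of which may be technical. Arrays are named by group and replicate number, a number that only names them.

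Total RNA was extracted with Trizol and labelled by Agilent's protocol for a single colour, per the labels' protocols. The arrays were read with Agilent Feature Extraction 10.7.1.1, per the file headers. The deposited spot intensities used here are the processed signal, which the scanner software had background-subtracted and detrended within the array but not normalized between arrays, and the median signals of the spot and of its local background. Each array held 43803 spots that were not controls, for 43603 probes, and 50 probes were spotted more than once, up to 5 times. The series also has a table of deposited log2 values with 15 columns. All 15 columns held the same sorted values within a tolerance of 0.001, and these differed by at most 0.000128 from the mean of the sorted log2 processed signals. That tolerance was set after the largest gap had been seen. Each column had a median of 4.80, and the Spearman correlation of each column with the log2 processed signal of its own array rounded to 1. The table thus holds log2 signals that were quantile-normalized over all spots, not centred by gene, and with the direction of the processed signal; the method that made it is not given in the sources used here.

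The main setting was the log2 processed signal minus the 75th percentile of each array over spots that were not controls. Spots that the scanner software marked as outliers were set missing, and spots of a probe were averaged. No probe was saturated on any array. Probes well above background on at least 4 arrays were tested, 34943 in number. Gene names came through RefSeq accessions without versions, matched to a table of the GRCz12tu assembly: 25978 of 27593 probes with such an accession were named, and probes with other kinds of accession stayed unnamed. The files use an older build, so no coordinates are printed.

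Groups were compared with limma 3.58.1 in R 4.3.3, with all 15 arrays in a single fit of 3 group means, moderated statistics that are two-sided, and Benjamini-Hochberg adjustment over the probes of a contrast at a threshold of 0.05. Fold changes are differences of mean log2 signals, and their errors are standard errors (SE) from that fit. Gene lists were written before the data were examined: 36 lists with 1511 entries, of which 1210 were on the array. They cover pathways of liver and markers of other cells, and each had at least 5 tested genes. Lists were tested with limma's camera at a preset correlation between genes of 0.01, on the brightest tested probe of each of 11819 named genes, with adjustment over the 36 lists. Missing values were filled with the mean of the probe in its group for these tests. Camera was repeated with an estimated correlation, fry was run beside it, and the list score (the mean log2 signal of the tested genes of a list on an array) was compared between groups by an exact permutation test over arrays, two-sided, which was chosen after seeing the data. Where array weights, a random block or a variance trend were used, the list test ran on the moderated statistics (cameraPR). Medians of lists are over the fitted log2 changes of the tested genes.

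A probe that was not well above background on any array of a group has only a bound there. The bound sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest signal among spots well above background and the probe's own signal. Where a gene was well above background on only some arrays of a group, their number is given beside its difference, which then rests in part on signals near background. A fit in which each signal below the lowest one well above background on its array, its floor, was set to that floor was added after seeing the data.

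The genes named follow a rule fixed before the data were examined: per contrast and direction the 10 genes that passed with the largest change, made up to 10 by the smallest p where fewer passed; all tested genes of the estrogen response list; up to 4 genes with the smallest p from each other list; and actb1, actb2, eef1a1l1 and gapdh as references. As no probe passed, the first part rests on the smallest p alone. From the up to 4 genes per list, those printed were picked after their values were seen. Some genes that the rule gives are not reported here. Where probes of a gene differ in direction, this is said beside the gene.

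The step from normalized values to calls was tested on simulated data for high against control with 200 changed probes among 34943. Of the 50 probes at each simulated log2 change, 2% were called at a change of 1, 54% at 2, 86% at 4 and 96% at 8, with 11 calls among unchanged probes. In simulated data for low against control, a list moved by a log2 change of 1 was recovered with a camera adjusted p of 2.06e-10, and 1 of 34 lists that shared no gene with it was also called. Noise was drawn for each probe independently, whereas genes of a list varied together in the data (estimated correlation 0.590 for the moved list, cell cycle). The simulation therefore does not show how often camera calls unchanged lists in these data.

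Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, each array's median as the scale, the deposited table, filters on dim probes, slide as a fixed or random block, array weights, a variance trend with robust moderation, the arrays of only the compared groups, other thresholds, and each array left out in turn. Normexp was planned on the mean spot signal, which the files do not hold as a column, and was run on the median spot signal. A fit with an oocyte score per array as a covariate, and the list tests with each array left out, were added after seeing the data. The number of arrays limits the precision of all values.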

Results

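The livers of male zebrafish kept without chlorothalonil (6 arrays, control) were compared with those of fish exposed to a low (5 arrays) or a high (4 arrays) concentration of the fungicide. The study asked how the exposure alters gene expression in the liver, with estrogen-like action named in its title. Arrays were spread over 4 slides, of which 3 held all 3 groups and slide 2 held control and low arrays. Between 65.3% and 77.4% of spots were well above background. The 75th percentile of the processed signal was 367 ± 43.4 (SD, n = 4) on high arrays, 245 ± 82.6 (SD, n = 6) on control arrays and 169 ± 30.0 (SD, n = 5) on low arrays. High arrays were brighter than control arrays (exact permutation p = 0.0333) and than low arrays (exact permutation p = 0.00794), and low and control arrays did not pass the threshold (exact permutation p = 0.0844). Correlations between pairs of arrays ran from 0.841 to 0.958, so no 2 arrays were duplicates. The first principal component, the axis of largest variation between arrays, held 32.6% of the variance and parted the arrays across groups. Control 2, high 1, high 2, low 1, low 3, low 4 and low 5 scored 72.1 to 177 on it, and all others -136 to -42.1. Estrogen response scores were 4.70 to 7.69 on the former and -0.45 to 3.30 on the latter. Group means therefore mix both kinds of array.

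In livers at the high concentration, genes of the egg envelope, of the ovary and of the cell cycle gave higher signals than in control livers, and genes of glutathione metabolism, of the proteasome, of iron handling and of muscle gave lower signals. Each of these list calls was lost with an estimated correlation (adjusted p = 0.812 to 0.849), and normexp background correction ended those of glutathione and iron genes and turned the proteasome list relative to all probes. The egg envelope gene zp3, a glycoprotein of the coat around the egg, averaged 1.88 ± 3.9 (SD, n = 4) on the log2 scale against -4.47 ± 3.18 (SD, n = 6) in controls, a log2 difference of 6.35 ± 2.16 (SE). It was well above background on 3 of 6 control arrays, and the difference was 5.63 with dim signals set to the floor of their array, an alternative chosen after seeing the data. The epithelial keratin gene krt5 averaged -3.53 ± 0.90 (SD, n = 4) against 0.44 ± 1.34 (SD, n = 6), a difference of -3.97 ± 0.67 (SE). No single probe passed: limma called 0 of 34943 probes, with a smallest adjusted p of 0.119, against 212 (93 higher, 119 lower) with array weights. Those weights were 2.04 and 2.25 for high 3 and high 4, 0.967 and 0.794 for high 1 and high 2, and 0.475 for control 2, the lowest of all arrays. At an unadjusted p under 0.05 there were 4088 probes (2007 higher, 2081 lower).

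The 10 named genes with the smallest p among those with higher values at the high concentration were efcab7, p4htma, abca5, ankfy1, ctdspl2b, gcna, rnls, zc4h2, nipsnap1 and foxa1. Log2 differences were 1.87 ± 0.34 (SE) for efcab7, 2.07 ± 0.41 (SE) for abca5, a transporter of the ATP-binding cassette family, 2.31 ± 0.46 (SE) for gcna, and 2.34 ± 0.51 (SE) for foxa1, a forkhead transcription factor of endoderm and liver. The probes of ankfy1 spanned -0.42 to 1.46 and those of ctdspl2b -0.08 to 1.28, and ctdspl2b stood at -0.31 with normexp, which moved the median of all probes to -0.50. The 10 with lower values were tnni2b.2, krt5, pvalb4, zfand5b, vps25, krt96, epg5, slc25a25b, higd1a and ube2al. The troponin gene tnni2b.2, well above background on 0 of 4 high and 4 of 6 control arrays, was at least 2.05-fold dimmer (limma adjusted p = 0.119), and epg5, well above background on 0 of 4 high and 5 of 6 control arrays, at least 2.66-fold. The p of tnni2b.2 rests on signals below the floor. With dim signals at the floor the limma adjusted p was 0.286 for tnni2b.2 and 0.127 for epg5. Log2 differences were -2.73 ± 0.51 (SE) for pvalb4, a parvalbumin, -3.02 ± 0.59 (SE) for krt96, -1.78 ± 0.35 (SE) for zfand5b and -3.62 ± 0.78 (SE) for higd1a, a mitochondrial gene known for its induction by hypoxia. Of these, efcab7 was well above background on 5 of 6 control arrays, pvalb4 on 1 of 4 and krt96 on 2 of 4 high arrays. In the main fit, adjusted p for these 20 genes ran from 0.119 to 0.185 in limma.

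Estrogen response genes as a list did not pass the test at the high concentration. The median of the 10 tested genes was 1.15, with 9 higher, a camera adjusted p of 0.161 and an exact permutation p of 0.538 for the list score. Vitellogenins are egg yolk precursors that the liver makes under estrogen. Their log2 differences were 1.47 ± 2.96 (SE) for vtg2, 2.01 ± 2.45 for vtg4, 1.85 ± 2.32 for vtg5, 2.08 ± 2.42 for vtg6 and 1.55 ± 1.87 for vtg7. The estrogen receptor genes gave 0.73 ± 1.24 (SE) for esr1, 0.82 ± 0.49 for esr2a and 0.73 ± 0.66 for esr2b. The aspartic protease gene nots gave 0.84 ± 2.31, and the aromatase gene cyp19a1b gave -0.31 ± 1.18 with 1 of 4 high and 1 of 6 control arrays well above background. Of the 10 genes, 0 passed over all genes and 0 adjusted over the list alone. The list median was 2.5 without control 2 (camera adjusted p = 0.00514), 2.74 without high 3 (adjusted p = 0.00401) and 0.65 without high 2, and 1.51 with normexp (adjusted p = 0.0227). It was 1.28 with slide as a block, and higher within 3 of 3 slides (0.90 to 4.04). Ovary and egg genes, markers of another tissue, had a median of 2.49. With the score of 19 oocyte genes as a covariate, chosen after seeing the data, the estrogen median turned to -1.04 (adjusted p = 0.532), with vtg2 at -2.31, vtg4 at -1.20, esr1 at -0.56 and nots at -1.70. Without high 2, vtg2, esr1 and nots turned to -0.39, -0.47 and -1.32.

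Of 36 lists, 12 passed camera at the high concentration, 4 higher and 8 lower. The egg envelope list (12 genes, all higher) rose with a median of 4.74 (adjusted p = 4.76e-07, and adjusted p = 0.812 with an estimated correlation). Of its genes, 0 passed over all genes and 7 adjusted over the list alone. The ovary and egg list (22 genes, 19 higher) rose with a median of 2.49 (adjusted p = 4.69e-07, and adjusted p = 0.812 with an estimated correlation). Among them slbp2, a binding protein of histone messenger RNA in the egg, was at least 7.19-fold brighter with 3 of 4 high arrays well above background. The gene h1m, a linker histone of the oocyte, gave 3.34 ± 1.46 (SE), with 4 of 6 control arrays well above background, and ca15b 4.82 ± 1.83 (SE), with 1 of 6. With dim signals at the floor ca15b gave 3.81. Cell cycle genes (46, of which 43 higher) rose with a median of 1.3 (adjusted p = 1.97e-08, and adjusted p = 0.812 with an estimated correlation). The mitotic kinesin gene kif11 gave 1.99 ± 0.77 (SE) and tyms, thymidylate synthase, 2.67 ± 1.05 (SE), with 5 and 4 of 6 control arrays well above background. With slide as a block the medians of these 3 lists were 4.90, 2.34 and 0.96, and all 3 were higher within 3 of 3 slides. With normexp the medians were 2.24, 0.56 and 0.16, or 2.74, 1.06 and 0.66 relative to all probes, with the calls kept. Without high 1 the ovary median was 1.33. With the oocyte score as a covariate the medians were 0.80, -0.041 and 0.40 and all 3 calls were lost. That score is the mean of 19 of the 22 tested ovary and egg genes, so the loss of the ovary list was fixed in advance. It holds no gene of the egg envelope or cell cycle list. The list of endoplasmic reticulum folding (62 genes, 44 higher) rose with a median of 0.30 (adjusted p = 0.00118), a call lost with an estimated correlation (adjusted p = 0.967 with an estimated correlation) and with slide as a block (median 0.04, adjusted p = 0.757). Without high 2 it was lost too, with medians of 0.19 (without control 4) to 0.63 (without high 1) as each array was left out, and 0.57 without control 5. The median was 0.58 with normexp and 0.48 with quantile normalization. Its members kdelr3 and stt3a, a retrieval receptor and a glycosylation subunit, gave 2.06 ± 0.61 (SE) and 0.83 ± 0.37 (SE).

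Glutathione and Nrf2 genes fell at the high concentration with a median of -0.67 (51 genes, 6 higher, camera adjusted p = 4.20e-07, and adjusted p = 0.812 with an estimated correlation). Among them gclm, a subunit of the enzyme that begins glutathione synthesis, gave -3.20 ± 1.07 (SE), hmox1a, heme oxygenase, -3.00 ± 1.24 (SE), and gsta.2, a glutathione transferase, -3.84 ± 1.08 (SE). As gsta.2 was well above background on 1 of 4 high and 4 of 6 control arrays, its difference was -3.02 with dim signals at the floor. The metal and iron list (16 genes, 3 higher) fell with a median of -1.04 (adjusted p = 0.00928, and adjusted p = 0.812 with an estimated correlation). The ferritin gene fthl28 gave -3.20 ± 1.17 (SE) and the iron exporter gene slc40a1 -2.28 ± 0.83 (SE). The muscle list (29 genes, 5 higher) fell with a median of -0.45 (adjusted p = 8.85e-05, and adjusted p = 0.812 with an estimated correlation). Of its genes, actc1b, a cardiac actin, gave -3.06 ± 0.72 (SE), pvalb2 -2.75 ± 0.66 (SE) and ckma, muscle creatine kinase, -1.88 ± 0.49 (SE). On high arrays these were well above background on 2, 1 and 3 of 4, and with dim signals at the floor they gave -2.71, -2.32 and -1.79. A second probe of ckma gave 0.06. With slide as a block the medians of these 3 lists were -0.52, -0.86 and -0.12, and within slides the glutathione list was higher on 0, the iron list on 1 and the muscle list on 2 of 3 slides. With normexp the calls of the glutathione list (median -0.49, adjusted p = 0.101) and of the iron list (median -0.85, adjusted p = 0.339) were lost, and relative to all probes the glutathione list stood at 0.0088. The muscle median was -0.88 with normexp and -0.27 without control 3, and the iron median -0.67 without high 2.

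The proteasome list (46 genes, 6 higher) fell with a median of -0.57 (adjusted p = 4.69e-07), while normexp turned its direction relative to all probes (median -0.19, adjusted p = 0.815), and psmd4b and psma6b gave -1.23 ± 0.43 (SE) and -1.10 ± 0.38 (SE). The call was lost with an estimated correlation (adjusted p = 0.849 with an estimated correlation). Ribosomal protein genes (83, of which 6 higher) fell with a median of -0.24 (adjusted p = 0.00196), turned to 0.18 with normexp (adjusted p = 4.58e-04), and stood at 0.0046 with quantile normalization (adjusted p = 0.996) and at -0.03 in the deposited table (adjusted p = 0.687). The adjusted p of the ribosomal list was 0.967 with an estimated correlation, and its call was lost without control 2 (medians of -0.33 to -0.12 over arrays left out). Calls for 3 further lists were lost as well, with adjusted p = 0.812 to 0.818 with an estimated correlation: biliary and epithelial genes fell by 0.56 (18 genes), p53 and apoptosis genes by 0.32 (44 genes) and endocrine pancreas genes by 0.66 (12 genes), with gcgb, a glucagon gene, at -2.08 ± 0.84 (SE). The gene gcgb was well above background on 3 of 4 high and 4 of 6 control arrays. Blocking on slide, the medians of these 3 lists were -0.26, -0.33 and -0.23, and the biliary and endocrine calls were lost (adjusted p = 0.0874 and 0.247). Within slides the biliary, ribosomal and endoplasmic reticulum lists were higher on 1 of 3 slides, and the p53, endocrine and proteasome lists on 0 of 3. With normexp the biliary and p53 lists turned to 0.061 and 0.32 relative to all probes and were not called (adjusted p = 0.170 and 0.631). Calls were also lost without control 4 or high 2 for the biliary list, without high 1, high 2, control 4, control 5 or control 6 for the p53 list, and without control 1, control 2, control 4, high 2, high 3 or high 4 for the endocrine list. Over all arrays left out their medians ran from -0.61 to -0.34 (without control 4), from -0.46 to -0.21 (without control 6) and from -1.02 (without high 1) to -0.55. The p53 median was -0.18 with normexp and -0.19 with quantile normalization, and with dim signals at the floor its call was lost (median -0.32, adjusted p = 0.10). With the oocyte covariate the p53 call was lost (median -0.16, adjusted p = 0.221), and the proteasome and iron medians were -0.31 and -0.61. Over all 12 calls, fry and the permutation of list scores left 0 past an adjusted p of 0.05, with a smallest permutation adjusted p of 0.294. Adjusted over the list alone, 5 muscle genes, 1 biliary gene and 1 ovary gene passed, and over all genes 0 did. With normexp 12 lists passed as well, 9 higher and 3 lower.

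**Figure D1:**
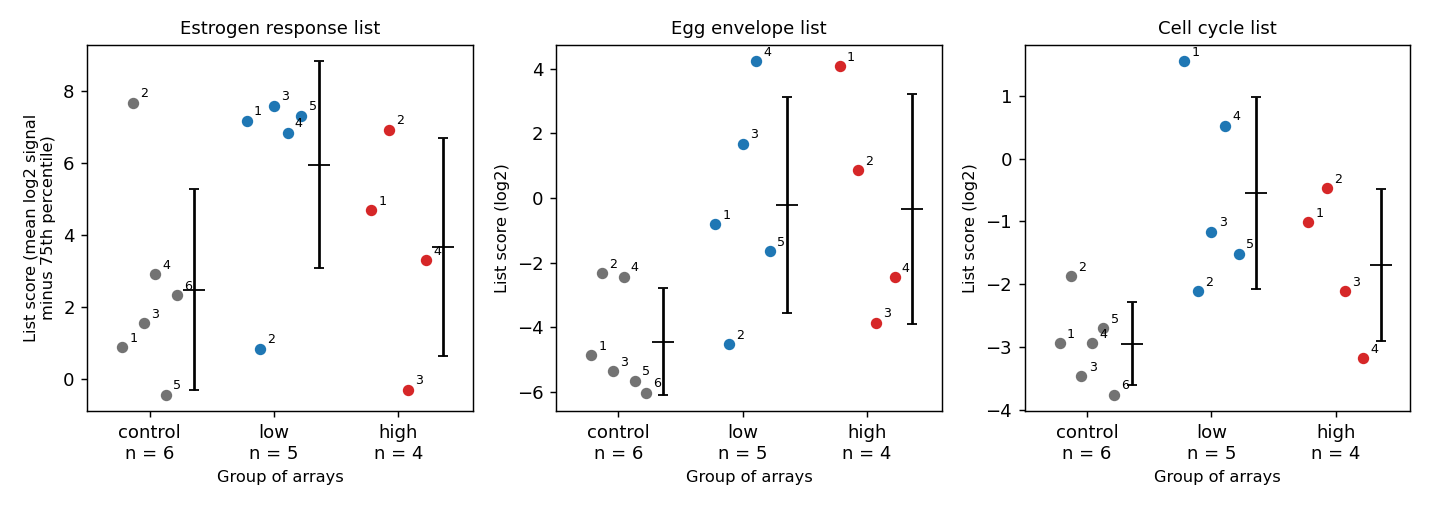
List scores (vertical axis, mean log2 signal of the tested genes minus the 75th percentile of the array) of estrogen response, egg envelope and cell cycle genes for control (n = 6), low (n = 5) and high (n = 4) arrays; points are arrays with their replicate number, and bars are the mean and SD. The estrogen score of control 2 was 7.69 beside -0.45 to 2.90 on the other controls, and that of low 2 was 0.84 beside 6.85 to 7.60 on the other low arrays.

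In livers at the low concentration, cell cycle, egg envelope, ovary, estrogen response, cholesterol synthesis and secretory pathway genes gave higher signals than in control livers, and genes of glutathione metabolism, glycolysis and blood gave lower ones. Each of these list calls was lost with an estimated correlation (adjusted p = 0.414), and that of blood genes with normexp. On the first principal component control 2 lay with low 1, low 3, low 4 and low 5, and low 2 with the other controls. The differences thus rest in part on how many arrays of each kind a group held. The mitotic kinesin gene kif11 averaged 1.29 ± 1.32 (SD, n = 5) on the log2 scale against -3.79 ± 0.97 (SD, n = 6) in controls, 33.8-fold brighter (limma adjusted p = 0.134), with 5 of 6 control arrays well above background. The oocyte gene slbp2 was not well above background on any of 6 control arrays and was at least 32.3-fold brighter on low arrays (limma adjusted p = 0.142). With dim signals at the floor its limma adjusted p was 0.201. The signal of vtg2 averaged 9.36 ± 4.85 (SD, n = 5) against 3.77 ± 5.02 (SD, n = 6), a spread nearly as wide as the difference of 5.59 ± 2.78 (SE). limma called 0 of 34943 probes, with a smallest adjusted p of 0.134 and 5336 probes at an unadjusted p under 0.05 (2781 higher, 2555 lower).

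The 10 named genes with the smallest p among those with higher values were kif11, slbp2, tm7sf2, mad2l2, sars2, zc4h2, neil3, dnaaf10, tonsl and fance. Log2 differences were 2.17 ± 0.42 (SE) for tm7sf2, a sterol reductase, 3.64 ± 0.76 (SE) for neil3, a DNA glycosylase, and 2.25 ± 0.50 (SE) for fance of the Fanconi anemia pathway, while tonsl, a factor of replication fork repair, was at least 2.91-fold brighter with 2 of 5 low and 0 of 6 control arrays well above background. Of 6 control arrays 5 were well above background for neil3. The 10 with lower values were krt5, zfand5b, tp53inp1, tnni2b.2, actc1b, klf5l, nudt17, tbc1d17, csrp1b and peli1b. Log2 differences were -3.44 ± 0.63 (SE) for krt5, -1.67 ± 0.32 (SE) for zfand5b, -2.65 ± 0.53 (SE) for tp53inp1, a p53 target, and -3.23 ± 0.67 (SE) for actc1b. As actc1b was well above background on 1 of 5 low arrays, its difference was -2.09 with dim signals at the floor. Bounds were at least 1.91-fold dimmer for klf5l and at least 1.05-fold for tnni2b.2 (4 of 6 control arrays well above background), and their fitted differences were 0.06 and 0.04 with normexp, which moved the median of all probes to 0.17. With dim signals at the floor the limma adjusted p was 0.273 for klf5l and 0.830 for tnni2b.2. In the main fit, adjusted p of these 20 genes ran from 0.134 to 0.204 in limma. The count of called probes was 151 with slide as a block (111 higher, 40 lower), 77 without low 2 (30 higher, 47 lower), 2 without control 2 and 1 without high 3.

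Estrogen response genes rose at the low concentration by camera, with a median of 3.94 over 10 genes, all higher (adjusted p = 2.42e-04). The call was lost with an estimated correlation (adjusted p = 0.414 with an estimated correlation), and the exact permutation test of the list score gave p = 0.0844. Of the 10 genes, 0 passed over all genes and 0 adjusted over the list alone. Log2 differences were 4.90 ± 2.3 (SE) for vtg4, 4.44 ± 2.17 for vtg5, 4.81 ± 2.27 for vtg6 and 3.43 ± 1.76 for vtg7. They were 5.32 ± 2.17 (SE) for nots, 2.29 ± 1.24 for esr1, 0.98 ± 0.46 for esr2a, 0.91 ± 0.61 for esr2b and 2.1 ± 1.11 for cyp19a1b. The last was well above background on 4 of 5 low and 1 of 6 control arrays, and gave 1.29 with dim signals at the floor. Without the vitellogenins, whose sequences are alike, the list median is the value of cyp19a1b itself, 2.1 (adjusted p = 0.00932), or 1.29 with dim signals at the floor (adjusted p = 0.0123). The list was higher within 4 of 4 slides (1.75 to 8.32), with a median of 4.24 with slide as a block, and 5.58 without low 2. Ovary and egg genes, markers of another tissue, moved with it (median 2.63, 22 genes), and with the oocyte score as a covariate the estrogen median was 0.87 (adjusted p = 0.353). In that fit the medians were 1.32 for cell cycle genes (adjusted p = 1.62e-13), 0.98 for cholesterol genes (adjusted p = 0.00212) and 0.64 for secretory pathway genes (adjusted p = 9.24e-10). The calls of egg envelope genes (-0.055) and ovary genes (-0.071) were lost, the latter by construction, as the score is made of ovary list genes.

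Of 36 lists, 20 passed camera at the low concentration, 7 higher and 13 lower. All 46 cell cycle genes were higher, and the list rose with a median of 2.47 (adjusted p = 1.23e-23, and adjusted p = 0.414 with an estimated correlation). Over all genes 0 of them passed, and 40 did adjusted over the list alone, with tyms at 4.03 ± 0.99 (SE) and 4 of 6 control arrays well above background for it. Egg envelope genes rose with a median of 4.76 (12 of 12 higher, adjusted p = 6.57e-07, and adjusted p = 0.414 with an estimated correlation). For zp3 the difference was 6.25 ± 2.02 (SE) and for zp2.2 it was 5.40 ± 1.95 (SE). Well above background were 4 of 5 low arrays for each, 3 of 6 control arrays for zp3 and 4 of 6 for zp2.2, and with dim signals at the floor they gave 5.52 and 5.03. Ovary and egg genes rose with a median of 2.63 (21 of 22 higher, adjusted p = 1.79e-08, and adjusted p = 0.414 with an estimated correlation), with h1m at 4.21 ± 1.37 (SE) and ca15b at 5.12 ± 1.71 (SE). On control arrays h1m was well above background on 4 of 6 and ca15b on 1 of 6, on low arrays ca15b on 4 of 5, and with dim signals at the floor ca15b gave 4.41. Adjusted over the list alone, 8 genes of each of these 2 lists passed, and 0 over all genes. Secretory pathway genes rose with a median of 0.69 (54 of 62 higher, adjusted p = 6.54e-09, and adjusted p = 0.414 with an estimated correlation). Its member fkbp11, a folding enzyme, gave 3.32 ± 0.92 (SE), kdelr3 2.33 ± 0.57 (SE) and stt3a 1.5 ± 0.34 (SE). Cholesterol genes rose with a median of 1.11 (20 of 27 higher, adjusted p = 1.58e-04, and adjusted p = 0.414 with an estimated correlation). The genes dhcr7, ebp and mvk, which encode enzymes of sterol synthesis, gave 2.23 ± 0.59 (SE), 2.45 ± 0.70 (SE) and 1.99 ± 0.56 (SE). Adjusted over the list alone, 5 secretory genes and 10 cholesterol genes (9 higher) passed, and 0 over all genes. Blocking on slide, the medians of these 5 lists were 2.70, 5.08, 2.77, 0.66 and 1.24. They were lower with normexp, at 1.22, 2.59, 1.23, 0.45 and 0.65, with the calls kept, and the cholesterol median was 1.87 without low 5. Within slides, cell cycle, egg envelope and ovary genes were higher on 4 of 4 slides, and secretory and cholesterol genes on 3 of 4. Ribosomal protein genes (83 of 83 higher) rose with a median of 0.48 (adjusted p = 2.27e-11), a call lost with an estimated correlation (adjusted p = 0.530 with an estimated correlation), with normexp (median 0.21, adjusted p = 0.0625) and in the deposited table (median 0.05, adjusted p = 0.127). Its median was 0.09 with quantile normalization and 0.31 without low 5.

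Glutathione and Nrf2 genes fell at the low concentration with a median of -1.02 (51 genes, 4 higher, adjusted p = 2.55e-09, and adjusted p = 0.414 with an estimated correlation). Heme oxygenase hmox1a gave -3.83 ± 1.16 (SE) and gclm -2.46 ± 1.0 (SE). Erythrocyte genes fell with a median of -0.78 (3 of 23 higher, adjusted p = 4.81e-04, and adjusted p = 0.414 with an estimated correlation). Glycolysis and gluconeogenesis genes fell with a median of -0.48 (10 of 39 higher, adjusted p = 0.00104, and adjusted p = 0.414 with an estimated correlation), with fbp1b, an enzyme of gluconeogenesis, at -1.61 ± 0.50 (SE). The list of other drug metabolism cytochromes fell with a median of -0.38 (6 of 33 higher, adjusted p = 9.74e-04, and adjusted p = 0.414 with an estimated correlation). Here nr1i2, the pregnane X receptor, gave -2.12 ± 0.54 (SE) and cyp3a65 -2.63 ± 0.78 (SE). With slide as a block the medians of these 4 lists were -1.08, -0.85, -0.52 and -0.50, and all 4 lists were lower within 4 of 4 slides. With normexp the call for erythrocyte genes was lost (median -0.011, adjusted p = 0.0938), as it was with the oocyte covariate (median 0.0026, adjusted p = 0.175). That covariate left glutathione genes at -0.58. Without control 6 the erythrocyte median was -0.50, and without control 5 that of the cytochromes was -0.63. The other lists that fell were those of biliary and epithelial cells (median -0.32, with krt8 at -1.55 ± 0.45, SE), stellate and endothelial cells (-0.40), p53 and apoptosis (-0.37), proteasome (-0.32), plasma proteins (-0.28, with the vitamin D binding protein gene gc at -1.24 ± 0.32, SE), muscle (-0.38), intestine (-0.49), bile acids (-0.40) and metal and iron (-0.50). Their adjusted p was 0.00104 to 0.0292 by camera and 0.414 to 0.780 (adjusted p) with an estimated correlation. In a fit with slide as a block their medians were, in that order, -0.41, -0.47, -0.41, -0.40, -0.29, -0.47, -0.49, -0.42 and -0.58, and within slides the muscle list was higher on 2 of 4, the proteasome and intestine lists on 1 of 4 and the other 6 on 0 of 4. Adjusted over the list alone, 6 biliary genes, 1 muscle gene and 1 drug metabolism gene (lower) and 1 p53 gene (higher) passed. Calls were lost with normexp for stellate (adjusted p = 0.0694), bile acid (0.0561), intestine (0.138) and muscle genes (0.624), and with quantile normalization for proteasome (0.386) and iron genes (0.0796, median -0.38). The last 2 were also lost in the deposited table (0.346 and 0.0764, with an iron median of -0.42). Normexp medians were 0.04 for muscle (-0.13 relative to all probes), -0.04 for stellate, -0.16 for bile acid, -0.12 for intestine, -0.17 for p53, -0.55 for plasma protein and -0.51 for proteasome genes. The proteasome median was -0.10 with quantile normalization and -0.13 in the deposited table. With the oocyte covariate the calls of p53, proteasome, plasma protein, intestine, bile acid and iron genes were lost (medians of -0.20 to 0.018, adjusted p = 0.0719 to 0.571), and the stellate and muscle medians were -0.08 and -0.23 with the calls kept. Leaving out single arrays ended the calls of stellate genes (control 4), p53 genes (control 5), intestine genes (low 4), plasma proteins (control 1, low 1 or low 4) and muscle genes (control 1, control 2, control 3 or low 1). It also ended those of proteasome genes (control 3, control 5, control 6, low 3 or low 5), bile acid genes (control 3, control 6, low 1, low 3 or low 4) and iron genes (control 3, control 4, control 5, low 1, low 3 or low 4). Over these 8 lists medians without 1 array ran from -0.82 to -0.16. Moves by over 1.5 times were those of biliary genes (-0.54 without control 2, -0.56 without low 2), stellate genes (-0.21 without control 4, -0.25 without low 4), p53 genes (-0.22 without low 1), intestine genes (-0.82 without control 6) and plasma proteins (-0.46 without low 2, -0.16 without low 4). The others were those of proteasome genes (-0.53, -0.19 and -0.20 without control 2, control 3 and control 6) and muscle genes (-0.21, -0.62, -0.59 and -0.20 without control 1, control 6, low 3 and low 4). fry and the permutation of list scores left 0 of the 20 calls, with a smallest permutation adjusted p of 0.117.

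**Figure D2:**
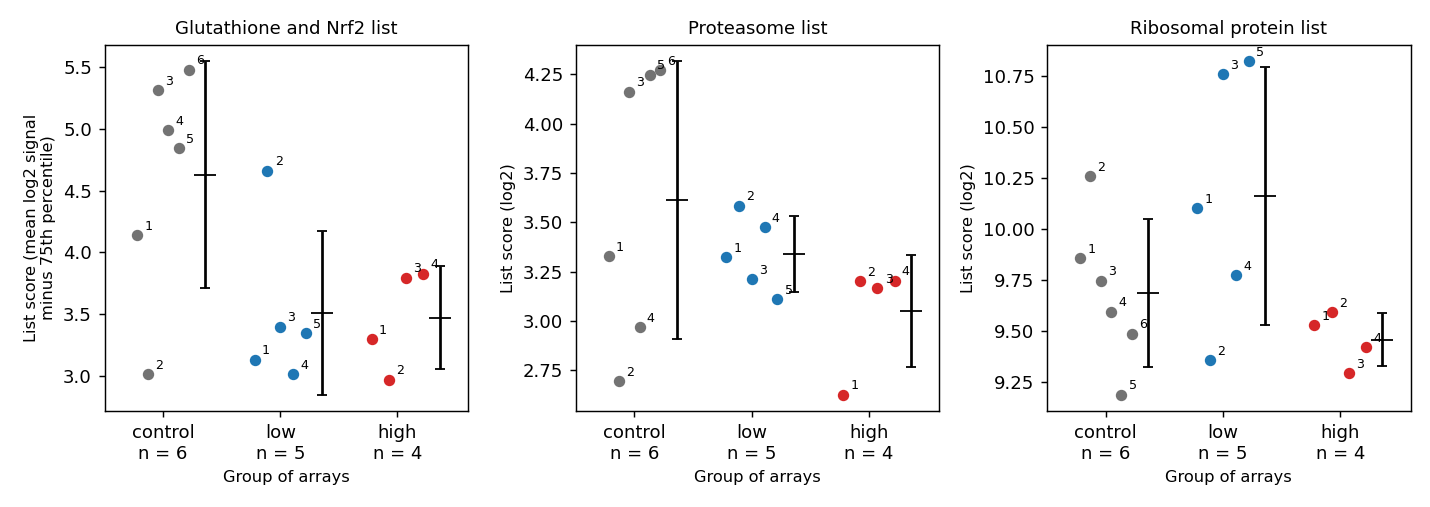
List scores (vertical axis, mean log2 signal of the tested genes minus the 75th percentile of the array) of glutathione and Nrf2, proteasome and ribosomal protein genes for control (n = 6), low (n = 5) and high (n = 4) arrays; points are arrays with their replicate number, and bars are the mean and SD. The glutathione score was 4.63 ± 0.92 on control, 3.51 ± 0.66 on low and 3.47 ± 0.41 on high arrays; for proteasome and ribosomal genes the direction between high and the other groups turned with normexp relative to all probes.

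Between the 2 concentrations, ribosomal protein, cell cycle, cholesterol and estrogen response genes gave lower signals at the high than at the low concentration, and bile acid genes gave higher ones. Ribosomal protein genes fell with a median of -0.72 (0 of 83 higher, camera adjusted p = 1.42e-31, and adjusted p = 0.907 with an estimated correlation), but normexp turned their direction relative to all probes (median -0.04, adjusted p = 0.115). Their median was -0.06 with quantile normalization (adjusted p = 0.00874) and in the deposited table (adjusted p = 0.0114). Cell cycle genes fell with a median of -1.19 (1 of 46 higher, adjusted p = 1.31e-08), cholesterol genes with a median of -1.02 (adjusted p = 6.26e-06) and estrogen response genes with a median of -2.5 (0 of 10 higher, adjusted p = 0.0154), each with adjusted p = 0.907 with an estimated correlation. Bile acid genes rose with a median of 0.75 (13 of 17 higher, adjusted p = 5.22e-04, and adjusted p = 0.907 with an estimated correlation). With slide as a block the medians of these 5 lists were -0.66, -1.72, -1.04, -2.75 and 0.98. Within slides, ribosomal, cell cycle and estrogen response genes were lower on 3 of 3 slides, cholesterol genes on 2 of 3, and bile acid genes were higher on 3 of 3. With dim signals at the floor the bile acid median was 0.14 (adjusted p = 0.00243) and the estrogen call was lost (median -2.24, adjusted p = 0.0545). With normexp the calls for cholesterol genes (median -0.67, adjusted p = 0.373) and bile acid genes (median 0.16, adjusted p = 0.0563) were lost, as was that for estrogen response genes (median -1.73, adjusted p = 0.435). The estrogen call was also lost without low 1, low 4 or high 3, with medians of -3.88 (without low 2) to -0.66 (without high 3) as each array was left out. The cell cycle median was -0.60 without low 1 and -0.60 without high 4, the cholesterol median -1.71 without low 5 and the bile acid median 1.14 without low 2.

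limma called 0 of 34943 probes between the 2 concentrations, with a smallest adjusted p of 0.835 and 1963 probes at an unadjusted p under 0.05. Among the named genes with the smallest p and higher values at the high concentration were golph3l, mgat4b, aldh4a1, fuca1.1, ugp2a, klf5l, phospho2, lrrc17 and ak4. Log2 differences were 3.84 ± 0.95 (SE) for mgat4b, a glycosyltransferase that was well above background on 3 of 5 low arrays, and 2.2 ± 0.59 (SE) for ugp2a, an enzyme of glycogen synthesis; those of golph3l and klf5l turned to -0.89 each with normexp, which moved the median of all probes to -0.59. Both genes were dim on low arrays, and with dim signals at the floor golph3l gave 0.39 and klf5l 0.64. Those with lower values were vsnl1a, chrm5b, cdx4, sox17, bicc2, ccn4b, ttll6, gfap, kif11 and cdh12a, with kif11 at -3.09 ± 0.80 (SE) and sox17 at least 3.23-fold dimmer with 0 of 4 high and 4 of 5 low arrays well above background. Adjusted p of these genes was 0.835 in limma. Floors were -5.96 to -5.66 on high and -5.20 to -4.39 on low arrays, so a probe at background reads lower on high arrays. Signals of chrm5b were -6.62 to -5.87 on high and -5.10 to -4.50 on low arrays. With dim signals at the floor chrm5b gave -1.21 and cdx4 -1.08. Differences of such dim genes, and part of the bound of sox17, may come from the floors and not from expression. Against control, probes of golph3l differed in direction at the high concentration, and those of lrrc17 and gfap at the low. The second probe of golph3l gave -0.82 at the high and -0.20 at the low concentration against control. Between concentrations it was thus lower at the high, opposite to the named probe. A probe of gfap gave -0.65 at the low concentration, below all gfap probes at the high (-0.62 to -0.22), so it too went opposite to the named probe. In all, 14 of 36 lists passed camera, 8 higher and 6 lower, which became 11 higher and 4 lower with normexp and 5 higher and 6 lower with quantile normalization. Without low 4, 9 passed. Over all genes and adjusted over the list alone, 0 members of the 14 lists passed. The further lists were higher for fatty acid oxidation (0.22), glycolysis (0.25), plasma proteins (0.27), growth hormone, insulin and thyroid (0.26), stellate and endothelial cells (0.32), erythrocytes (0.27) and drug metabolism cytochromes (0.09, with a mean of -0.00217). They were lower for secretory pathway (-0.27, turned with normexp to 0.22) and proteasome genes (-0.26, turned with normexp to 0.28). Their adjusted p was 0.00417 to 0.0431 by camera and 0.907 to 0.927 (adjusted p) with an estimated correlation. In a fit with slide as a block their medians were, in that order, 0.27, 0.41, 0.43, 0.48, 0.43, 0.52, 0.45, -0.50 and -0.33. Within slides each kept its direction on 3 of 3 slides, except erythrocyte and proteasome genes, which did so on 2 of 3. With dim signals at the floor the secretory and proteasome calls were lost (adjusted p = 0.0623 and 0.0619). With normexp the calls for stellate (adjusted p = 0.584) and erythrocyte genes (adjusted p = 0.780) were lost, with medians of -0.24 and -0.34 that lay 0.36 and 0.25 above that of all probes. The medians were then 0.78 for fatty acid oxidation, 0.92 for plasma proteins, 0.54 for growth hormone, insulin and thyroid and 0.53 for drug metabolism cytochromes. Quantile normalization ended the calls for growth hormone, insulin and thyroid genes (adjusted p = 0.0781), drug metabolism cytochromes (0.107) and erythrocyte genes (0.0524), as did the deposited table (0.0719, 0.103 and 0.0545). Their medians were 0.30, 0.10 and 0.39 with the first and 0.30, 0.10 and 0.40 in the second. The plasma protein median was 0.50 with quantile normalization. With the oocyte covariate the calls for the cytochromes (median 0.11, adjusted p = 0.0576) and erythrocyte genes (median 0.19, adjusted p = 0.0731) were lost. Of these lists, fatty acid oxidation and stellate genes kept their call without any 1 array, and the other 7 lost it for at least 1 array. These were glycolysis genes (high 1), secretory genes (high 1, high 3 or low 4), proteasome genes (high 1, low 2 or low 4), growth hormone, insulin and thyroid genes (high 1, high 4, low 2 or low 4) and plasma proteins (high 1, high 3, high 4, low 1 or low 4). Erythrocyte genes lost it without high 3, high 4, low 2, low 3 or low 4, and drug metabolism cytochromes without high 1, high 3, high 4, low 1, low 3 or low 4. Medians without 1 array ran from 0.11 (high 3) to 0.35 (high 1) for fatty acid oxidation, from 0.06 (low 1) to 0.48 (high 2) for glycolysis, from 0.10 (low 4) to 0.54 (high 2) for plasma proteins and from 0.15 (low 4) to 0.38 for growth hormone, insulin and thyroid genes. They ran from 0.17 (high 4) to 0.40 for stellate, from 0.06 (high 4) to 0.72 (high 2) for erythrocyte and from 0.09 to 0.34 (low 2) for cytochrome genes, from -0.50 (high 4) to -0.12 (high 1) for secretory and from -0.32 to -0.13 (high 1) for proteasome genes.

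The log2 changes of both concentrations against the same controls correlated across 34943 probes (r = 0.696), where probes are not independent replicates. Simulated unchanged groups against shared controls gave a mean r of 0.427 (highest 0.458 of 100). Simulated probes were drawn independently of one another, unlike real ones, so the simulated r varied too little to test the observed r against. The covariance was 0.517, against 0.160 in the simulation, a difference of 0.357. With the 6 controls split 3 and 3 between the contrasts, over 10 splits and 20 assignments, r averaged 0.409 (0.244 to 0.581) and the covariance 0.358. limma called 0 probes in either contrast, so 0 were called in both. Reference genes gave log2 differences of 0.91 ± 0.40 (SE) and 1.01 ± 0.38 (SE) for actb1 at the high and low concentration, 0.12 ± 0.34 and -0.41 ± 0.32 for actb2, -0.16 ± 0.31 and 0.38 ± 0.30 for eef1a1l1, and -0.21 ± 0.29 and 0.33 ± 0.27 for gapdh. The signs for eef1a1l1 and gapdh turned at both concentrations with quantile normalization. With normexp the signs for eef1a1l1 and gapdh turned at the high concentration only. Probes differed in direction among themselves for actb1 at both concentrations, for actb2 and eef1a1l1 at the high and for gapdh at the low.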

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

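In this part the tests of the ovary, exposure and exchange explanations and the oocyte covariate were chosen after the results were seen. A sample was singled out where its gap to the nearest other sample of its group, over the range of the group, passed Dixon's critical value for that number of samples. Of 405 groups of values examined, 32 values met this, where chance, which flags about 1 in 20 groups, gives 20.25. Related genes and the list scores that hold them vary together, so the groups are not independent. The count is therefore not a test against chance.

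Low 2 lay apart from the other low arrays most often. Its log2 signals were 0.73 for vtg2, 2.2 for vtg4, 2.09 for vtg5, 2.36 for vtg6, 4.38 for vtg7 and 1.72 for nots, while the nearest other low array reached 10.71, 11.06, 10.87, 11.31, 10.96 and 7.98. They were 5.30 for stt3a, 0.61 for kdelr3, 4.55 for fkbp11 and -2.64 for gcna, all lower, and 5.07 for gclm, 2.75 for psmd4b and -1.25 for peli1b, all higher. Its score was 0.84 for the estrogen response list, the lowest of the group, and 4.66 for the glutathione and Nrf2 list, the highest. Control 2 lay above the other controls for nots (10.5, nearest 1.74), cyp19a1b (-2.38) and tyms (-1.43).

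High 2 lay apart from the other high arrays for ghra (2.49), fkbp11 (7.94), and the scores of the p53 and apoptosis list (0.60) and the apolipoprotein and plasma protein list (6.32). High 1 had the lowest proteasome score (2.62), and high 4 the highest score of androgen and steroid metabolism (1.41). Among controls, control 3 was low for efcab7 (-5.21), control 1 high for pvalb2 (-1.58), control 4 high for tp53inp1 (4.13) and for the stellate and endothelial score (-0.020), and control 5 low for the androgen and steroid score (0.68) and high for the secretory pathway score (4.60). Among low arrays, low 1 was high for ctdspl2b (-2.76) and low 3 low for aldh4a1 (1.13).

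Estrogen response genes were brighter on most exposed arrays, with control 2 at a score of 7.69 and low 2 at 0.84. Exposure alone, the biological explanation, is neither excluded nor borne out: 1 control array lay at or above the median score of the 9 exposed arrays, and at least 2 were set as the number that would exclude it. Ovary tissue or female fish among the arrays stays open, as the score of 19 oocyte genes, of which 8 to 13 were well above background on each control array too, lay above the highest control on 6 exposed arrays. With that score as a covariate the medians became -1.04 (high) and 0.87 (low), though the score itself differs between groups and can take up an effect of exposure. On control 2, whose estrogen score was the highest of all arrays, the oocyte score was -3.33, within the range of the other controls (-4.58 to -3.32). The 2 scores thus went apart there, and a single array does not settle the question for the others. An exchange of control 2 and low 2, the only arrays of different groups whose titles share a number, also stays open. Arrays were placed on an axis of 100 probes from controls (0) to high arrays (1). On the axis built without control 2, control 2 lay at 0.789, low 2 at 0.243 and the other low arrays at 0.780 to 0.967. For each other control or high array the axis was rebuilt without that array, with control 2 kept among the controls. There the other controls lay at 0.0171 to 0.400, and high 3 and high 4 at 0.206 and 0.353, values not strictly comparable with that of low 2. On the first principal component, common to all arrays, high 3 (-79.7) and high 4 (-42.1) lay on the side of low 2 (-97.3). A place near the controls is thus not peculiar to low 2, and no array was regrouped.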

How the results depend on the processing

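The oocyte covariate, setting dim signals to the floor of their array, the permutation of list scores and, for lists other than estrogen response, leaving out arrays were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers that pair arrays across groups; a single title number is shared, by control 2 and low 2.

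In limma the count of called probes, 0 in each contrast, became 151 (low against control, slide as a block), 212 (high against control, array weights), 2 (low against control, only those arrays) and 4049, 5243 and 1955 for high and low against control and high against low at an unadjusted p under 0.05 with a change of at least 1.5-fold. It stayed 0 at an adjusted p under 0.1 and with all other settings. Leaving out arrays gave 0 to 77 for low against control (77 without low 2, 2 without control 2, 1 without high 3) and 0 for the other contrasts. With the oocyte covariate it was 0, with 2671, 1645 and 1865 probes at an unadjusted p under 0.05; that count was 7895, 2676 and 14279 with normexp, 6356, 7380 and 6031 with array weights, and 4868, 6228 and 4763 with no filter.

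The estrogen median at the high concentration was 1.51 with normexp, now past the threshold, and turned to -1.04 with the oocyte covariate; leaving out arrays gave 0.65 to 2.74. At the low concentration it was 0.87 with that covariate, no longer past the threshold, 3.94 with the call lost under an estimated correlation (adjusted p = 0.414), and 3.13 to 5.58 leaving out arrays, all past it. With the oocyte covariate 11 lists passed at the low concentration in place of 20. The egg envelope list, which shares no gene with the covariate, turned at the low concentration (-0.055). The ovary list turned at both (-0.041, high, and -0.071, low), but the covariate is made of its genes, so the loss of its call was fixed in advance. Leaving out arrays gave 11 to 14, 16 to 21 and 9 to 16 lists for the 3 contrasts. Camera's 12, 20 and 14 lists became 0 with an estimated correlation, which by construction allows for genes that vary together between arrays, and 0 by permutation, where the number of arrays bounds the smallest p. Splitting controls moved r from 0.696 to 0.409, in a split that also leaves fewer controls per contrast.

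Normexp moved the median of all probes to -0.50, 0.17 and -0.59, median scaling moved that of low against control to -0.12, and no filter gave -0.11, 0.11 and -0.17. The normexp offset of 50 was large beside the median processed signals of the arrays (17.6 to 52.2), and an offset changes dim signals most. The effects of the background correction and of its offset were therefore not told apart. Relative to its median, normexp turned the ribosomal list to 0.68 (median 0.18, high against control) and 0.55 (-0.041, high against low), the proteasome list to 0.31 (-0.19) and 0.87 (0.28) and the secretory list to 0.81 (0.22). The erythrocyte list (median -0.34, high against low) stayed above it by 0.25, while the test's direction turned lower; the cause was not tested.

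Of 3707 values of named genes under alternatives, 3636 kept direction and side, 40 passed the threshold and 31, in 15 genes, turned. The cause was not tested. Many of these genes were named for their small p in these same data, and no probe passed in the main fit. Keeping direction and side was therefore likely from the start and does not measure reliability. Normexp gave, against control, -0.31 for ctdspl2b, 0.23 for eef1a1l1 and 0.21 for gapdh (high), and 0.041 for tnni2b.2 and 0.058 for klf5l (low), and -0.89 for klf5l and -0.89 for golph3l between concentrations; relative to the median of all probes ctdspl2b, tnni2b.2 and the low value of klf5l kept their side. Quantile normalization gave eef1a1l1 0.15 (high) and -0.10 (low) and gapdh 0.028 and -0.13; the deposited table gave eef1a1l1 0.13 and -0.10 and gapdh 0.027 and -0.15; slide as a block gave gapdh 0.0082 (high). The oocyte covariate gave, at the high concentration, esr1 -0.56, vtg2 -2.31, vtg4 -1.20, vtg5 -1.25, vtg6 -1.16, vtg7 -0.91 and nots -1.70. At the high concentration, leaving out arrays gave cyp19a1b -1.23 to 0.46 (0.28 without high 1, 0.46 without control 2, 0.0094 without high 3) and actb2 -0.081 to 0.47 (below 0 without high 1 or control 2). It gave esr1 -0.47 to 1.51, vtg2 -0.39 to 4.13 and nots -1.32 to 2.47, each below 0 without high 2 alone. Dim probes such as tnni2b.2 and klf5l are limited by signal over background.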

Other observations

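In this part the tests of the muscle explanation, of splits at an adjusted p and of splits within slides were chosen after the results were seen; those of array brightness and of splits at an unadjusted p without regard to slide were not.

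Receptors of growth hormone and a growth factor of the liver had higher values at the high concentration than in controls. Log2 differences were 1.44 ± 0.41 (SE) for ghra, 1.53 ± 0.49 (SE) for ghrb and 1.70 ± 0.50 (SE) for igf2b, with limma adjusted p of 0.277, 0.310 and 0.292. The glucocorticoid receptor gene nr3c1 gave 0.86 ± 0.31 (SE, adjusted p = 0.334). The list of growth hormone, insulin and thyroid genes did not pass camera against control (median 0.06, adjusted p = 0.195), so these genes do not stand for their list.

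Several lists passed in no contrast. At the high and low concentration against control, medians were -0.07 and -0.34 for the aryl hydrocarbon receptor list, -0.13 and -0.15 for androgen and steroid metabolism, -0.37 and -0.22 for heat shock, 0.0016 and -0.03 for lipogenesis, -0.08 and -0.10 for acute phase and complement, 0.07 and 0.10 for interferon, -0.16 and -0.14 for inflammation, -0.13 and -0.17 for oxidative phosphorylation, 0.04 and -0.33 for glucocorticoid response, and -0.12 and -0.04 for the circadian clock. Markers of other cells in the same order were -0.48 and -0.36 for exocrine pancreas, -0.06 and 0.04 for leukocytes and -0.05 and 0.41 for testis and germ line. Camera's direction was opposite to the median for lipogenesis in both contrasts and for glucocorticoid response and testis at the high concentration.

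Muscle genes as a list had medians of -0.45 and -0.38 at the high and low concentration, calls that were lost with an estimated correlation (adjusted p = 0.812 and 0.596) and, at the low, with normexp (adjusted p = 0.624), and within slides the list was higher on 2 of 3 and 2 of 4 slides. Muscle carried over onto control livers is a candidate explanation that this test could not settle: of 29 tested muscle genes, 58.6% were lower in both contrasts against control, which lies between the shares set for and against carry-over. The list's brightest genes in controls, eno3 and gapdh at a log2 signal of 10.33 each, encode enzymes of glycolysis that liver expresses too. The muscle actin gene acta1a averaged 4.70 in controls and gave 0.05 and -0.54 at the high and low concentration, while actc1b, ckma and pvalb2 averaged -2.54, -3.19 and -3.38 in controls. No biological explanation was tested.

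Ribosomal protein genes were brighter on low than on high arrays, and low arrays were the dimmest. The list median of -0.72 lay at percentile 0 of 10000 random lists of the same mean signal, which spanned -0.39 to 0.03. A median outside that range had been set as the outcome against array brightness. The test cannot decide this, because members of the random lists were drawn independently of one another. Ribosomal protein genes varied together between arrays (estimated correlation 0.867), so medians of unrelated genes spread too little to stand for them. Array brightness stays open, since the median was -0.064 with quantile normalization and -0.055 in the deposited table, which equalize signals between arrays. The background correction, with its offset, stays open too, because with normexp the list median of -0.041 stood above the median of all probes. Exposure as the biological explanation cannot be set apart from these choices here.

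Chance could not be excluded for the counts of probes fitted without slide. Among 100 splits of the arrays of each contrast, drawn without regard to slide, with missing spots filled, the real split included, 5 gave at least as many probes at an unadjusted p under 0.05 and 1.5-fold for high against control (real 4061, highest other 5378), 6 for low against control (real 5264, highest other 8547) and 24 for high against low (real 1971, highest other 6052). At an adjusted p under 0.05 the real counts were 0, which any split reaches (100 of 100 in each contrast), so that comparison decides nothing. The highest of the other splits called 5, 2314 and 401 probes there, which points to some structure of the samples. With slide as a block, all 72 splits of low and control arrays within slides were examined. At an adjusted p under 0.05, 1 of them, the real split, gave at least as many probes (real 151, highest other 8). At an unadjusted p under 0.05 and 1.5-fold, 4 of 72 did (real 6196, highest other 7807). The block was taken up for this test after it had called 151 probes where most other settings called 0. The splits make no allowance for that choice, so chance is not excluded here either.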
